A study of Mus musculus with 10 samples.

How the data were processed

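Total RNA from the border area of the ventricle of male C57BL/6 mice had been taken 21 days after surgery, per the labels' protocols, and the series' design text gives the same interval as 3 weeks. The mice had either a myocardial infarction (MI, death of heart muscle after its blood supply is blocked) or a sham operation. Each of the 10 samples, 5 per group, was hybridised to 1 Agilent array with a single dye, Cy3, per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say outright that each sample came from a separate animal, so p-values measure the spread between these samples.

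The scanner files were made with Agilent Feature Extraction 10.7.1.1, per the file headers. They hold spot intensity on a linear scale, and the deposited processed signal intensity has had background and spatial trends removed by that program but has not been scaled between arrays. The files also give flags of 0 or 1 for spots well above background, saturated or uneven, as deposited by the authors. The submitters' processing notes name RMA with neither a role nor a version. The deposited value table of the series holds log2 values. Each of its columns correlated best with the log2 processed signal of its own array, with r between 0.993 and 1.000 across probes, and all 10 columns had a median of 3.41, so its scale was log2 with equal medians. Which steps led to it is not given in the sources used here.

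Each array carried 180870 spots, of which 175896 were not controls. They held 145548 probes of 60 bases, 142176 with 1 spot and 3372 with 10 spots, whose log2 values were averaged. Spots with outlier flags were left out, and 88 probes then lacked a value on some array. No probe had a genome coordinate, and the files do not pair probe IDs with genes. The IDs come in a catalogue form (51691 probes) and a custom form (93857 probes), and neither form was read as a class of transcript. Coding and noncoding transcripts could therefore not be counted apart, the 38 gene lists and cell type markers fixed before the data were examined could not be run, the genes fixed for naming (among them Postn, Tgfb1, Trp53, Col1a1 and Nppa) were not analysed here, and the same holds for noncoding transcripts and their neighbouring coding genes. Every probe was tested as a feature of its own. The mean of all probes of a gene, planned as an alternative, could not be run for the same reason.

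The log2 processed signal of each array was lowered by the array's 75th percentile over noncontrol spots. Probes well above background on at least 4 of the 5 arrays of at least 1 group were kept, which left 73893. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes, and probes with an adjusted p under 0.05 were called. A second count took called probes with a log2 fold change of at least 1 in size. The fit was tested on simulated data with 50 changed probes per fold size. With all 10 arrays it recovered 26% of 2-fold, 86% of 4-fold, 94% of 8-fold and 98% of 16-fold changes with 6 false calls. With slide 3 left out it recovered 56% of 2-fold and 96% of 4-fold changes with 8 false calls. With slide as a block, and no slide effect simulated, it recovered 0% of 2-fold, 16% of 4-fold, 56% of 8-fold and 84% of 16-fold changes with 5 false calls, and with slide 2 alone 0% at each size. The spread simulated for the blocked fit was that around the group means, which holds slide differences, so its recovery may be understated. In all these simulations the arrays were independent, and a probe had the same spread on every array. The real arrays were correlated within slides and differed in spread. The shares recovered and the false calls may therefore not hold for the real arrays.

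The file headers place the arrays on 3 slides read on 2 scan days. Slide 1 held sham replicates 1 to 4, slide 2 held sham replicate 5 and MI replicates 1 to 3, and slide 3, read on the second day, held MI replicates 4 and 5. Only slide 2 holds both groups. Slide was added to the fit as a fixed block, and also as a random block (consensus correlation 0.611). The comparison was also made within slide 2 and, apart from it, between slides 1 and 3. Same-numbered sham and MI arrays were checked for joint deviations from their group means, and since not every correlation was above 0.1 the numbers were not used as pairs.

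Array measures and control probes were compared with an exact two-sided permutation test of the difference of means over all 252 arrangements, whose smallest p is 0.00794. Principal components were taken from the tested probes, centred per probe. Sets of probes that differed on slide 2 were compared with 10000 seeded random sets matched on sham level, G and C content and ID form. Pairs of probes were found from exact sequence overlap of at least 25 bases on the same or on opposite strands.

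The rule for names, fixed before the data were examined, asked for called probes with a gene symbol whose MI and sham values do not overlap and which are well above background on all arrays of the higher group. With no symbols it took none. The 4 probes named here meet the rest of the rule and are the outermost 2 on each side among those well above background on at least 1 array of the lower group, and this choice was made after their values were seen.

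Alternatives fixed before the data were examined were scaling by the median, quantile normalization, normexp background correction (offset 50) of the mean and local background intensities followed by either scaling, the deposited value table, no filter on dim probes, a filter for probes well above background on all 10 arrays (53065 probes), trended and robust eBayes, array weights, blocks for replicate number and slide, and each replicate left out in turn. Further ones, chosen after seeing the data, left out slide 3 or compared slides apart. No spot was saturated on any array. The number of arrays and their signal over background limit the precision. Calculations outside limma used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.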

Results

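Coding and noncoding transcripts were profiled in ventricular border tissue of male C57BL/6 mice, 21 days after myocardial infarction (MI, 5 arrays) or a sham operation (5 arrays). The title of the series concerns a long noncoding RNA, lncPostn, in the signalling of TGF-beta and p53 during cardiac fibrosis, the scarring of heart tissue, and the design compares infarcted with sham hearts. Between 51.8% and 53.9% of noncontrol spots were well above background on the sham arrays. On the MI arrays the shares were 48.5%, 54.5% and 53.2% for replicates 1 to 3 and 40.1% and 42.1% for replicates 4 and 5.

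The comparison of MI with sham asked which transcripts differed in the infarcted heart. Of 73893 tested probes, 22 were higher and 14 lower in MI, and all 36 differed by at least 2-fold. The probe A_52_P220176 had a log2 signal relative to the array's 75th percentile of 3.17 ± 0.99 in MI and -0.71 ± 0.16 in sham (SD, n = 5 each), a log2 fold change of 3.88 (SE 0.39), or 14.7-fold (limma, adjusted p = 0.0150). A_51_P409010 was at 2.04 ± 2.13 in MI and -3.99 ± 1.10 in sham (SD, n = 5 each), a log2 fold change of 6.03 (SE 0.89; limma, adjusted p = 0.0474), although only 2 of the 5 sham arrays measured it well above background. On the lower side, CUST_OEV3_011140 was at -2.66 ± 0.64 in MI and -0.65 ± 0.12 in sham (SD, n = 5 each), a log2 fold change of -2.0 (SE 0.27; limma, adjusted p = 0.0388), with 2 of 5 MI arrays well above background. CUST_OEV3_062635 was at -1.32 ± 0.43 in MI and 0.34 ± 0.39 in sham (SD, n = 5 each), a log2 fold change of -1.67 (SE 0.25; limma, adjusted p = 0.0475), and its sham replicate 5 lay at -0.34, away from the other sham arrays. With normexp background correction and the 75th percentile the log2 fold changes were 2.73 for A_52_P220176, 2.66 for A_51_P409010, -0.60 for CUST_OEV3_011140 and -0.72 for CUST_OEV3_062635, and none of the 4 was called (limma, adjusted p from 0.0547 to 0.0983). The files do not pair these IDs with genes.

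**Figure D1:**
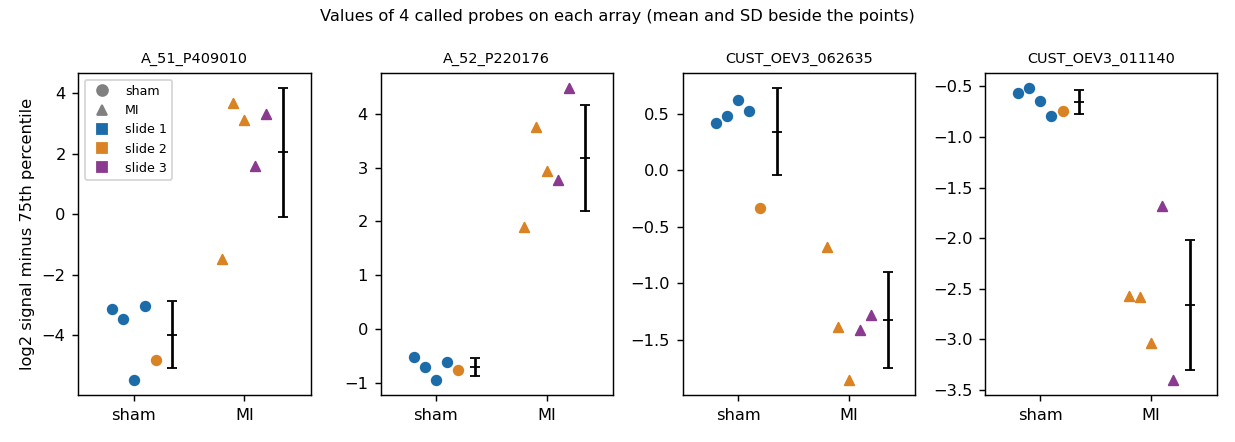
Log2 signal minus the array's 75th percentile (vertical axis) of 4 called probes on each sham (circles) and MI (triangles) array, coloured by slide, with the mean and SD of each group beside the points. In A_52_P220176 the 5 MI arrays lie between 1.90 and 4.48 and the 5 sham arrays between -0.95 and -0.52.

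In all 36 called probes the 5 MI values did not overlap the 5 sham values. Among all tested probes this held for 2791, and chance gives 0.794%. For 13 of the 36, no array of the lower group was well above background, so that their difference is only bounded. The number of calls was sensitive to single arrays. It was 0 without sham replicate 2, 3 or 4 or without MI replicate 3, with 7673, 7446, 7556 and 10488 probes at an unadjusted p under 0.05 (limma), against 10834 with all arrays. It was 2 without sham replicate 1, 25 without sham replicate 5, 19 without MI replicate 2, 147 without MI replicate 4, 18 without MI replicate 5, and 1228 without MI replicate 1, of which 871 were higher and 357 lower. Quantile normalization gave 5 higher and 5 lower, median scaling 12 higher and 7 lower, normexp with the 75th percentile 3 higher and 0 lower, and normexp with quantile normalization 2 higher and 3 lower. The 36 probes kept their direction under these 4 settings of background and scale, which hardly tests direction in probes chosen for large differences.

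Slide and group overlapped in this series, since slide 1 held only sham and slide 3 only MI arrays. With slide as a block limma called 0 probes, and 3350 (4.53%) had an unadjusted p under 0.05. On simulated data without a slide effect the blocked fit recovered 0% of 2-fold and 16% of 4-fold changes. The spread simulated there held the slide differences of the real arrays as noise, so these shares may be too low. They do not show how many changes the blocked fit missed here. With slide as a random block the count was 0, with 4312 probes at an unadjusted p under 0.05. Slide 2 alone, with 3 MI arrays and 1 sham array, was too small for such counts, since on simulated data its fit recovered 0% even of 16-fold changes. The differences within slide 2 were 3.63 for A_52_P220176, -1.99 for CUST_OEV3_011140 and -0.97 for CUST_OEV3_062635 on the log2 scale. A_51_P409010 was not well above background in sham replicate 5. With the block the adjusted p values in limma were 0.433, 0.808, 0.919 and 0.830 in this order.

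Slide 2 and the other slides also gave 2 comparisons of MI with sham that share no array. On slide 2, 180 probes were at least 2-fold higher in each of MI replicates 1 to 3 than in sham replicate 5. Of these, 77 were also at least 2-fold higher in both MI replicates 4 and 5 than the mean of sham replicates 1 to 4, or 42.8% against 3.95% of all tested probes. Random sets of the same size, matched on signal level, base composition and ID form, held a median of 14 such probes and at most 34 (one-sided permutation p = 0.0001, the smallest that 10000 sets can give). Probes are not independent replicates, so this p describes the sets and not the animals. A probe dim in sham passes the filter only if at least 4 of the 5 MI arrays measured it, which favours agreement between slides 2 and 3. Without the filter on dim probes the share was 24.2%, against 23.2% of all probes, and among probes well above background on all 10 arrays it was 48.8% (20 of 41), against 4.4%. Of 160 probes at least 2-fold lower in each of MI replicates 1 to 3, 18 were lower by as much in both other MI arrays, and matched sets held a median of 19 (one-sided permutation p = 0.7). This share of 11.3%, against 8.59% of all tested probes, was 33.8% against 15.9% without MI replicate 4 and 21.3% against 13.5% without MI replicate 5. Across all tested probes the differences of the 2 comparisons had a Pearson correlation of 0.147 and a Spearman correlation of 0.104. Without MI replicate 5 the Pearson correlation was -0.00422.

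**Figure D2:**
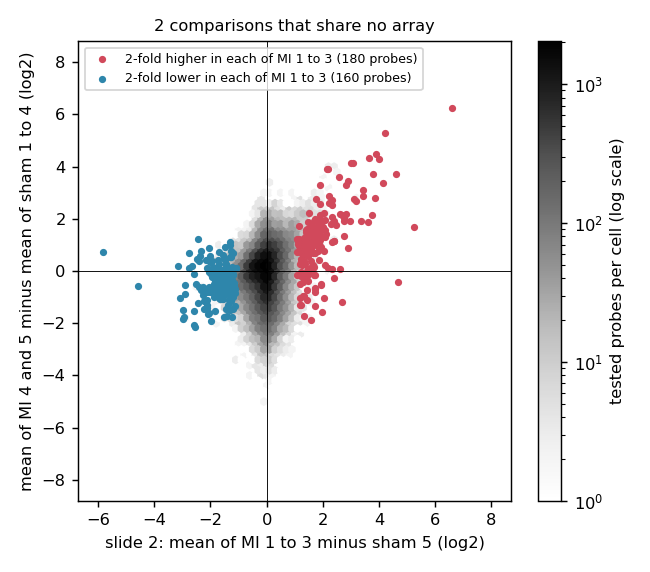
Each tested probe by its log2 difference between MI replicates 1 to 3 and sham replicate 5 on slide 2 (horizontal axis) and between MI replicates 4 and 5 and sham replicates 1 to 4 on slides 3 and 1 (vertical axis), with grey showing how many probes fall in a cell on a log scale. Red and blue points are the 180 and 160 probes at least 2-fold higher or lower in each MI array of slide 2, and 77 of the red points were at least 2-fold higher in both MI arrays of slide 3.

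The controls of the arrays include probes named for Gapdh and Pgk1, enzymes of glycolysis. Relative to the 75th percentile, Mouse-GAPDH_5 was at 10.37 ± 0.52 in MI and 10.68 ± 0.21 in sham (SD, n = 5 each; exact permutation p = 0.278, 0.614 after adjustment over the 4 control probes). Mouse-GAPDH_3 was at 8.59 ± 0.90 and 8.61 ± 0.18 (SD, n = 5 each; exact permutation p = 0.960). Mouse-PGK1_3 was at 7.01 ± 0.61 and 7.23 ± 0.12 (SD, n = 5 each; exact permutation p = 0.460), and Mouse-PGK1_5 at 4.32 ± 0.60 and 4.65 ± 0.16 (SD, n = 5 each; exact permutation p = 0.310). None of the 4 differences passed the test. Within slide 2 the mean of MI replicates 1 to 3 differed from sham replicate 5 by log2 differences of -0.25 for Mouse-GAPDH_3, -0.22 for Mouse-GAPDH_5, -0.33 for Mouse-PGK1_3 and -0.35 for Mouse-PGK1_5, with MI replicate 1 above sham replicate 5 in both Gapdh probes. MI replicate 4 was the highest array in all 4 probes. Without it, Mouse-GAPDH_5 differed by -0.51, Mouse-PGK1_3 by -0.47 and Mouse-PGK1_5 by -0.58 (exact permutation p = 0.0317, 0.00794 and 0.0159), and Mouse-GAPDH_3 by -0.35 (exact permutation p = 0.238).

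Array quality was compared between the groups. The median local background was 19.2 ± 3.49 intensity units in MI and 15.4 ± 0.894 in sham (SD, n = 5 each; exact permutation p = 0.0317, adjusted p = 0.0952 over 3 measures). It was 15 on slide 1, between 16 and 17 on slide 2 and 23 on slide 3. The percentage of spots well above background was 47.7 ± 6.45 in MI and 53.2 ± 0.849 in sham (SD, n = 5 each; exact permutation p = 0.143). Without MI replicate 2 or 3 its exact p was 0.0238 or 0.0476. The 75th percentile of log2 signal was 6.04 ± 0.41 in MI and 6.04 ± 0.20 in sham (SD, n = 5 each; exact permutation p = 0.976). Within slide 2 the background differed by -0.333 and the percentage by 0.210.

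Variation among the arrays followed the slides before the groups. The first principal component held 52.8% of the variance and separated MI replicates 4 and 5, with scores of 183 and 197, from the other 8 arrays, whose scores lay between -85.7 and -19.4. The second held 23.2%, with scores of 121 and 77.9 for MI replicates 2 and 3, 83.2 for MI replicate 5 and -44.3 for MI replicate 4. Sham replicates 1 to 4 lay between -61.3 and -47.3. MI replicate 1 scored -4.43 and sham replicate 5 scored -19.3, and these 2 arrays had a correlation of 0.989 across probes. Within the MI group, slide 3 against slide 2 gave 8895 probes higher and 12201 lower (limma). Within the sham group slide 2 holds 1 array, sham replicate 5, which is too few for such a count against slide 1.

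**Figure D3:**
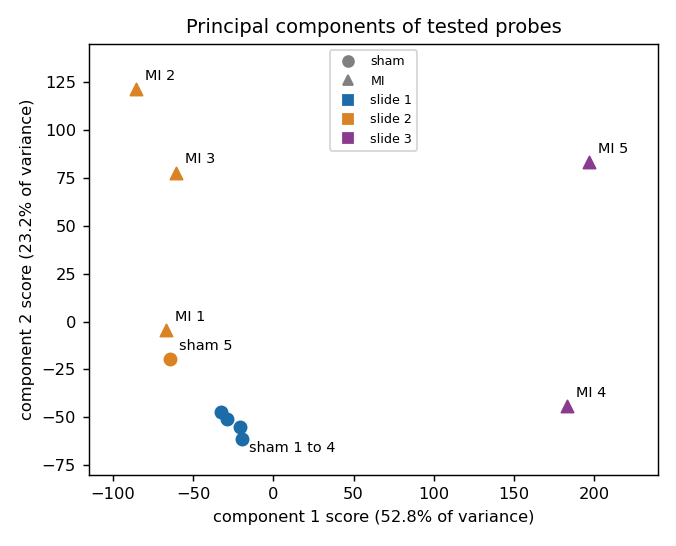
Scores of the 10 arrays on principal components 1 and 2 of the tested probes (no unit), with circles for sham, triangles for MI and colours for slides. MI replicates 4 and 5 sit at 183 and 197 on component 1, and MI replicate 1 sits beside sham replicate 5.

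Without MI replicates 4 and 5, an alternative chosen after seeing the data, 2461 probes were higher and 9616 lower in MI (limma, adjusted p under 0.05), 1908 of them by at least 2-fold, and all 36 probes were among them. With slide as a block in that set, 0 were higher and 1 was lower, with 5916 at an unadjusted p under 0.05. Among these arrays all 3 MI arrays, but only 1 of the 5 sham arrays, were on slide 2.

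**Figure D4:**
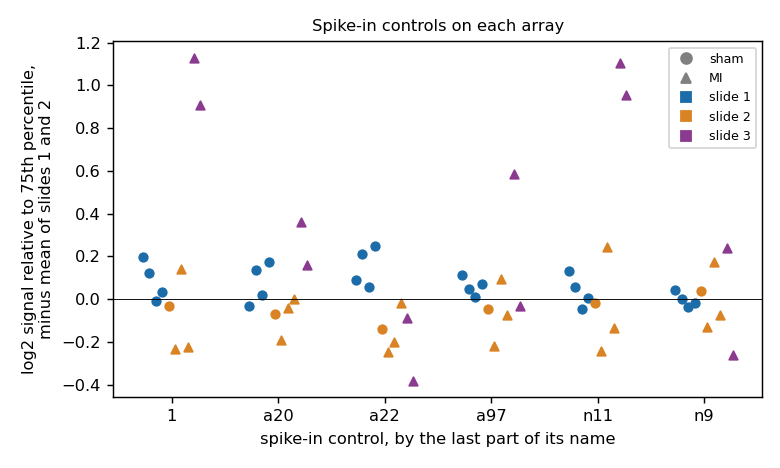
Log2 signal relative to the array's 75th percentile of the 6 spike-in controls that were well above background on every array, minus the mean of the 8 arrays of slides 1 and 2 (vertical axis), with circles for sham, triangles for MI and colours for slides. In the controls 1 and n11 both arrays of slide 3 lie above the other 8 on this scale, by a mean of 1.02 and 1.03, which does not hold for the signal before scaling.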

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

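The spike-in test of slide 3, the pairs of sham arrays set beside MI replicate 1 and the comparison without slide 3 were chosen after their values had been seen, and the level of each left-out sham array was added after that of sham replicate 5.

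Sham replicate 5 lay far from the other sham arrays in 5 of the 13 measures examined in that group. The rule took the gap to the nearest neighbour over the group's range. By chance some array of a group lies that far in about 1 in 20 measures, and a given array less often. These measures are not independent. Its median background was 17, against 15 on the other 4. It was at 8.30 in Mouse-GAPDH_3, 10.32 in Mouse-GAPDH_5, 4.37 in Mouse-PGK1_5 and -0.34 in CUST_OEV3_062635 (log2, relative to the 75th percentile). The lowest of the other sham arrays was at 8.64, 10.72, 4.67 and 0.42. It was the only sham array on slide 2.

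MI replicates 4 and 5, on slide 3, stood apart from the other 8 arrays. Brightness scale as the whole difference is argued against by quantile normalization, which left 17789 probes called between MI replicates 4 to 5 and MI replicates 1 to 3. A larger form of the slide 2 difference was tested by direction. Of 9265 probes at least 2-fold from sham in both arrays, 56.7% had the same direction on slide 2, below the bound set for this explanation. Those directions rest on 1 sham array and on no minimum difference on slide 2, so many may be noise. Of 180 probes 2-fold higher in each MI array of slide 2, 77 were 2-fold higher in both slide 3 arrays and 7 were 2-fold lower. Of 160 lower ones, 18 and 0 went the same and the opposite way. The test thus cannot decide on this explanation. Handling of slide 3 may account for part of the pattern, since 4 of 6 spike-in controls, which hold no heart RNA, had both slide 3 values outside the range of the other 8 arrays once each array's controls were set relative to their own mean (2 of 6 relative to the 75th percentile of heart probes, and 2 others with no scaling). Relative to their own mean, controls 1 and n11 deviated by 0.63 and 0.64 (log2) and a22 and n9 by -0.62 and -0.40. This scale ties the controls together, so a rise in some of them lowers the others. Relative to the 75th percentile a22 and n9 deviated by -0.23 and -0.01. A biological difference between these hearts and those of MI replicates 1 to 3 stays open beside handling of slide 3.

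MI replicate 1 lay close to sham replicate 5, which was on the same slide. Their correlation across probes was 0.989. With sham replicates 1 to 4 MI replicate 1 had correlations of 0.980 to 0.983, and with MI replicates 2 and 3 of 0.967 and 0.979. An exchange with sham replicate 5, which would turn their difference round, is argued against by 572 probes called without these 2 arrays, of which 73.6% kept their direction in MI replicate 1 minus sham replicate 5. A sham heart under an MI label stays open. On these 572 probes the 12 ordered pairs of sham replicates 1 to 4 gave at most 58.2%. On probes called without the pair they gave at most 68.4%, but those sets held only 34 to 48 probes. But on 27712 probes called between sham replicates 1 to 4 and MI replicates 2 and 3 the share of MI replicate 1 was 60.7%. That lies within the 32.5% to 67.5% of sham pairs on probes called without the pair, so the argument against an exchange is weaker there too. MI replicate 1 may also carry a smaller form of the change in MI replicates 2 and 3. Its median was 19% and 13.4% of theirs in the 2 sets of probes. Both values lie above the highest medians of the sham pairs. These were 3.28% and 9.26% on the same probes, and 7.5% and 9.21% on probes called without the pair. The single sham array on slide 2 keeps this explanation open too.

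The real division of the 10 arrays gave 36 called probes, and 1 of 100 divisions into 5 and 5 (the real one included) gave as many, with at most 1 in the others. Without slide 3 the real division gave 12077, and 1 of 56 divisions into 5 and 3 gave as many, with at most 1 in the others. Chance division of the arrays is thus argued against for both counts, though shares below 1 in 100 and 1 in 56 could not be reached. The divisions ignored the slides, which overlap the groups, so this says nothing of the slides. Slide 1 against slide 2 may be part of the second count. On 17665 probes called between sham replicates 1 to 4 and MI replicates 1 to 3, sham replicate 5 showed a median of 43.6% of the difference, and 29.5% on the 2582 of them at least 2-fold apart. Each of sham replicates 1 to 4, left out in turn, showed between -0.0126% and 14.1% on other sets of 1145 to 6480 probes, called without that array and without sham replicate 5. With 1 sham array on slide 2, the slide and the animal cannot be told apart.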

How the results depend on the processing

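The settings that add slide as a random block, scale to probes well above background on all arrays, leave slide 3 out, take slides apart or join normexp with a slide block, and all tests of probes that were 2-fold apart on slide 2, were chosen after seeing the data. The rest were fixed before the data were examined.

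All 36 called probes kept their direction with median scaling, quantile normalization, both normexp settings and the deposited value table. These settings hardly test direction, since the 36 probes were chosen from these arrays for large differences. Median scaling could turn none of them. It moved all log2 fold changes alike, their median from -0.089 to -0.169, and the smallest of the 36 in size was -1.18. With arrays left out or blocked the direction of the 36 probes was bound to hold, since their MI and sham values do not overlap. Their number, 22 higher, 14 lower and 36 at least 2-fold apart, did not hold. Given in that order, the counts were 12, 7 and 19 with median scaling, 5, 5 and 10 with quantile normalization and again 5, 5 and 10 with the deposited value table, 3, 0 and 1 with normexp and the 75th percentile, and 2, 3 and 2 with normexp and quantile normalization. They were 4, 0 and 4 with no filter on dim probes, 11, 2 and 13 with probes well above background on all 10 arrays, where 53065 probes, and 13 of the 36, were tested, and 19, 9 and 28 with trended and robust eBayes. Array weights, which gave MI replicates 4 and 5 weights of 0.101 and 0.117 and MI replicate 3 a weight of 3.70, raised them to 8234, 17815 and 3428. They were 20, 14 and 34 with the 75th percentile taken over probes well above background on all arrays. Leaving out each replicate in turn gave 0 to 871 higher, 0 to 357 lower and 0 to 1059 at least 2-fold apart. The highest came without MI replicate 1 and 0 calls without sham replicate 2, 3 or 4 or MI replicate 3, with 7673, 7446, 7556 and 10488 probes at an unadjusted p under 0.05 in limma. Apart from the weights and the fewer probes or arrays, the cause was not tested.

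With the replicate number as a block limma called 0 higher, 0 lower and 0 at least 2-fold apart, with 9286 probes at an unadjusted p under 0.05. Same-numbered arrays had correlations of -0.0983, -0.00359, -0.206, 0.216 and -0.336, and only replicate 4 of sham correlated best with its own number. No same-numbered arrays shared a slide and slide was not removed, so these values cannot rule out that the numbers pair the samples.

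With slide as a block the counts were 0, 0 and 0 (3350 probes at an unadjusted p under 0.05), as a random block 0, 0 and 0 (4312). Within slide 2 alone they were 0, 0 and 0 (2055), which says nothing of stability, since its fit recovered 0% even of 16-fold changes in simulated data. Slides 1 and 3 alone gave 13005, 15600 and 14309. Without slide 3 they were 2461, 9616 and 1908, with quantile normalization 2839, 6740 and 1689, with the deposited values of the series 2839, 6711 and 1687, without MI replicate 1 as well 6513, 15946 and 5620, and with slide as a block 0, 1 and 1 (5916). Normexp and quantile normalization with slide as a block gave 1, 3 and 4.

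The correlation between the 2 comparisons that share no array, 0.147, was 0.306 with normexp and the 75th percentile, 0.264 with normexp and quantile normalization and 0.265 for probes well above background on all 10 arrays. Leaving out replicates gave -0.00422 (without MI replicate 5, a change of sign) to 0.260 (without MI replicate 4). The share of 42.8% for probes higher on both (3.95% of all tested probes) was 20% of 10 probes (0.807% of all) with normexp and the 75th percentile and 22.2% of 9 (0.614%) with normexp and quantile normalization. It was 26.3% (1.98%) with the 75th percentile over probes well above background on all arrays and 24.2% (23.2%) with no filter. With replicates left out it was 34.7% (3.95%, without MI replicate 3) to 66.7% (10.4%, without MI replicate 4). The share of 11.3% for lower probes (8.59% of all) was 1.76% (4.87%) with no filter, 2.5% (2.84%) for probes well above background on all 10 arrays, and 6.40% (8.59%, without MI replicate 1) to 33.8% (15.9%, without MI replicate 4) with replicates left out. Sham replicate 5 could not be left out of these, being the only sham array on slide 2.

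Component 1 held 67.4% of the variance of the 1000 most variable probes, and 48.2% to 58.8% with replicates left out. With replicates left out, MI minus sham ranged from -7.18 to -3.59 for the percentage well above background, passing the exact test without MI replicate 2 or 3. For the median background it ranged from 2.85 to 4.60, missing the threshold without any one of sham replicates 1 to 4 (exact p = 0.0794). For the 75th percentile it ranged from -0.10 to 0.13. The offset of 50 added in the normexp correction in itself shrinks log2 differences of dim probes, and with them counts of probes 2-fold apart. The 4 named probes kept their direction with each other scaling. Their size was lower with the normexp correction, whose offset and background removal were not tested apart. With normexp and the 75th percentile their log2 fold changes were 2.66 for A_51_P409010, 2.73 for A_52_P220176, -0.60 for CUST_OEV3_011140 and -0.72 for CUST_OEV3_062635, and with slide as a block CUST_OEV3_062635 was at -0.97. Their smallest sizes under any setting were 2.66, 2.68, -0.55 and -0.38. A_52_P220176 stayed called in 18 of 31, with adjusted p from 1.47e-05 to 0.999 (limma), A_51_P409010 in 9 of 30, CUST_OEV3_011140 in 11 of 30 and CUST_OEV3_062635 in 11 of 31. Signal over background limits what dim probes can show, since on slide 3 over 50% of spots were not well above background.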

Other observations

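The test of opposite strands without slide 3 and the counts by ID form were chosen after the values had been seen.

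Probes with overlapping sequence on the same strand gave a check on single probes. Over all 10 arrays, 85.1% of 793 pairs of identical sequence under different IDs and 67.0% of 710 partly overlapping pairs had the same direction in MI minus sham. Random pairings gave at most 54.1% and 54.9% in their middle 95%. The pairs held 1303 and 1084 probes, so some shared a probe and these ranges may be too narrow. Without slide 3 the shares were 84.0% and 71.5%.

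Directions were counted by ID form, with no test of a difference between the forms. Of 18 called probes with catalogue-form IDs 16 were higher in MI, and of 18 with custom-form IDs 6 were. Among the 77 probes at least 2-fold higher in MI on slide 2 and again on slide 3, 59 had catalogue-form and 18 custom-form IDs, while the 180 probes they came from held 104 and 76. The 77 probes shared no overlapping sequence, and 14 of them were among the 36 called probes. The median log2 shift from sham replicates 1 to 4 was -0.32 for catalogue and 0.13 for custom forms in MI replicate 2, and 0.29 and -0.19 in MI replicate 4. These were the most extreme arrays. In the same order it was -0.14 and 0.04 in MI replicate 1, -0.22 and 0.08 in MI replicate 3, and -0.04 and -0.14 in MI replicate 5. Sham replicate 5, on slide 2 like MI replicates 1 to 3, was at -0.13 and 0.05. The shift on slide 2 was thus not particular to MI. Which transcripts the forms stand for was not settled here.

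A hypothesis was that transcripts on opposite strands of the same locus change together. Over all 10 arrays 77.6% of 210 pairs of probes on opposite strands had the same direction, above the 48.1% to 60.5% of random pairings. The pairs held 257 probes, so many shared a probe, and the ranges of random pairings given here may be too narrow. Without slide 3 the share was 46.7%, within the 43.8% to 56.2% of random pairings, while the differences of the pairs had a Pearson correlation of 0.285, outside the -0.136 to 0.136 of random pairings, and both pairs that were 2-fold apart in each probe had the same direction. Without these 2 pairs it was 0.198. Whether opposite strands change together is thus not settled. An effect of base composition on slide 3, which both strands of a locus share, may contribute, since G and C content had a rank correlation of -0.151 across probes with MI replicates 4 to 5 minus MI replicates 1 to 3, against 0.051 with MI replicates 1 to 3 minus sham. With MI minus sham over all 10 arrays, the difference that gave 77.6%, the rank correlation was -0.072. The value of -0.151 lies between the bounds set for and against this explanation, so the source stays open.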
